A study of Homo sapiens with 2 samples.

How the data were processed

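K562 cells, an established human chronic myeloid leukaemia line of erythroid character, were exposed to compounds in 96-well plates for 6 h, and their polyadenylated RNA was measured by MAC-seq. In this method reverse transcription gives each well its own barcode, all wells of a plate are pooled into 1 library, and the 3′ ends of the mRNAs are sequenced. ERCC RNAs, a set of synthetic transcripts, were part of the reverse transcription mix of every well, per the labels' protocols. Each treatment was run in technical duplicate, per the series description.

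The deposited files hold 1 table per plate with read counts per gene and well. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 2.1 and R 4.0.2 were used with genome build GRCh37 (hg19); the aligner, the counting program and the annotation are not given in the sources used here. The deposited values are of the kind called expected counts or estimated counts only in that some summary lines are fractional: every value of the 57905 gene lines and 92 ERCC lines is a whole count, and 6 summary lines were left out. The counts are taken as reads and not molecules: human counts per well were 83.9% to 88.9% of the deposited reads mapped to genes, while reads per unique molecular identifier ranged from 1.67 to 3.21 on plate 1 and from 1.63 to 3.53 on plate 2. Copies made by amplification therefore count more than once. A deposited annotation gives the compound name and barcode of each well, but no dose and no replicate number. Symbols were taken from a table of Ensembl identifiers, which named 51996 of the 57905 gene lines and 10103 of the 10312 genes tested; older symbols in the gene lists were matched through unique RefSeq synonyms of assembly GRCh38.p14, used for names only. No coordinates are given, because the reference at hand is of another build than the files.

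Both plates carry the same layout, so that the duplicate of a treatment lies in the well of the same number, with the same barcode, on the other plate. Counts of same-numbered wells had a chi-square per degree of freedom of 1.10 to 2.71 (median 1.43), and 0 of the 96 pairs were identical. Because copies of a molecule count more than once, sampling of molecules alone can raise this value above 1. The first plate column holds 8 wells per plate that are shallower than the others; they were kept, and its effect is given as a measured fact beside the results. Human counts per well run from 173553 to 1906446 and ERCC counts from 56920 to 237950.

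Genes were tested with edgeR 4.0.16 in R 4.3.3. Human genes were kept with filterByExpr at its defaults, TMM factors were computed over them, and 1 negative binomial model with a term per treatment and an additive plate term was fitted to all wells, so that treatments with 2 wells share the estimate of spread. The quasi-likelihood test compared each of the 74 treatments with the 24 DMSO wells, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. All wells passed the minimum of 10000 counts. The model was fitted with a faster solver of the same likelihood; over 300 genes its log2 fold changes differed from those of edgeR by at most 1.7e-07, and both called 142. On simulated counts of the 10312 genes, 200 of them changed, the comparison built like that of THZ531 (2 wells) recovered 31% of genes changed 2-fold and 72% of those changed 4-fold with 6 false calls, and the one built like that of AZ5576 (6 wells) recovered 66% and 89% with 11 false calls. A simulated unchanged treatment (2 wells) gave 0 calls with edgeR and 1 with limma-voom. The simulated wells held no effect of well position or barcode, which the duplicates of a treatment share. False calls from that source are therefore left out of these counts.

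Main comparisons, chosen by a rule fixed before the data were examined, are the first compound in alphabetical order of each of 8 target classes, among compounds classed beforehand: AZ5576 (CDK9), LDC4297 (CDK7), THZ531 (CDK12 and CDK13), OTS964 (CDK11), dBET1 (BET), A241 (CBP and p300) and Panobinostat (HDAC), while no compound was assigned to CDK8 and CDK19. No CDK9 compound classed beforehand was present, so AZ5576 was taken from those classed after the compound names were seen. HDAC compounds classed that late (MC1568, NexturastatA and others) did not count for the rule. Genes named are, per direction, drawn from the 10 largest changes past the threshold with a mean log2 CPM of at least 5 and the same sign in every treated well, and from the 2 to 4 members with the smallest p of each gene list called; for other treatments at most the top 3 per direction. MYC, MCL1, HEXIM1, GATA1, HBG1, FOS, JUN, CDKN1A and GAPDH were looked up everywhere. Gene families with near-identical members (globin, HSPA1A and HSPA1B, histone genes, pseudogene copies) can share reads at the 3′ end, so values within such a family are uncertain.

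Gene lists, fixed before the data were examined, were tested on the same model with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Adjustment ran over the 28 lists with at least 3 tested members. The preset treats the members of a list as nearly independent, so its p can be too small for genes that move together. Mitochondrial-encoded mRNAs, for example, were called up in 42 treatments with the preset, and in 11 of these with an estimated correlation too. Counts of members are given over all genes and adjusted over the list alone. Of the markers of other blood lineages, 0 of 17 megakaryocyte, 3 of 17 myeloid and 1 of 14 lymphoid genes passed the expression filter, and only 27 of 60 histone genes matched a line by name, of which 16 were tested. All histone values below cover polyadenylated RNA alone. They do not measure histone mRNA without a poly(A) tail. The ratio of human to ERCC counts was taken per well as log2 and compared with the DMSO wells of the same plate by a two-sided exact permutation test within plates, adjusted over the 74 treatments. Direct contrasts between compounds of 1 class used the same edgeR model. Correlations of log2 fold changes across genes were set against 20 simulations of unchanged groups sharing the DMSO wells.

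Alternatives tried before any result was chosen were DESeq2 size factors, ERCC scaling, library size alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 10 counts in at least 50% of the wells, a further threshold of 1 on the absolute log2 fold change, adjustment over all treatments together, a fit of a treatment and the vehicle wells alone, other well minima, no plate term, and leaving out wells 1 at a time; in the refits without wells the dispersion trend was held. Leaving out the first plate column, taking 39 other compounds as reference, and splitting compounds by well position were added after seeing the data.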

Results

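The data describe K562 cells 6 h after the addition of inhibitors of transcription and of chromatin regulators, a time at which mRNA levels follow synthesis and decay more than cell growth. The wells lie on 2 plates of 96, and both plates hold the same 74 treatments and DMSO, the vehicle. DMSO filled 12 wells per plate, 4 of them in the first column. Of the treatments, 68 had 1 position per plate, 2 had 2 and 4 had 3. Counts to human genes summed to 75315078 on plate 1, with 241202 to 1603856 per well (median 810105), and to 67819725 on plate 2, with 173553 to 1906446 per well (median 728691.5). Wells of the first column were shallower, with medians of 287063.5 and 255517.5 counts against 871562.5 and 755675 in the other columns. A median of 14743.5 and 14590 genes per well was detected on plates 1 and 2, and 10312 genes were tested. Because duplicates are technical, every p-value below measures only the spread between wells of 1 experiment. Doses are not given, so compounds set side by side cannot be matched for dose.

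Treatments ranged from 21 called genes (SGC_CBP30) to 4881 (AZ5576) against DMSO by edgeR's quasi-likelihood test, with a median of 109.5 over the 74 treatments. Low counts include an offset of the DMSO wells described below: EtOH gave 82 genes against DMSO and 0 against 39 other compounds. They therefore do not rank compounds by activity. Among the 4 compounds with the most calls, 3 block transcription or its kinases: AZ5576, actinomycin D (ActD, a DNA intercalator, 4457 genes) and DRB (an elongation inhibitor, 2942 genes). Okadaic acid, a phosphatase inhibitor, changed 3103 genes, and the HDAC inhibitors Quisinostat and Panobinostat 2081 and 1906. AZ5576 and ActD had 6 wells and the others named here 2, and with the 2 wells of single positions AZ5576 gave 2018 to 3229 genes and ActD 1904 to 2509, so the order depends on the number of wells. At least 1000 genes changed in 12 treatments and fewer than 100 in 36. Pairs of DMSO wells tested against the other DMSO wells gave a median of 0 calls over 80 draws by edgeR and also by limma-voom, with any call in 11 draws. All 7 draws that put both wells in the first column gave calls by edgeR (3 to 560, median 412), and the other draws gave at most 1 by edgeR and at most 6 by limma-voom. These draws pair different positions of 1 plate, whereas a treatment with 2 wells holds 1 position on both plates. Pairs of DMSO wells built that way, added after seeing the data, gave 0 to 394 genes over 12 positions (median 3), with 11 to 394 in the first column (median 231) and 0 to 12 elsewhere (median 0).

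**Figure D1:**
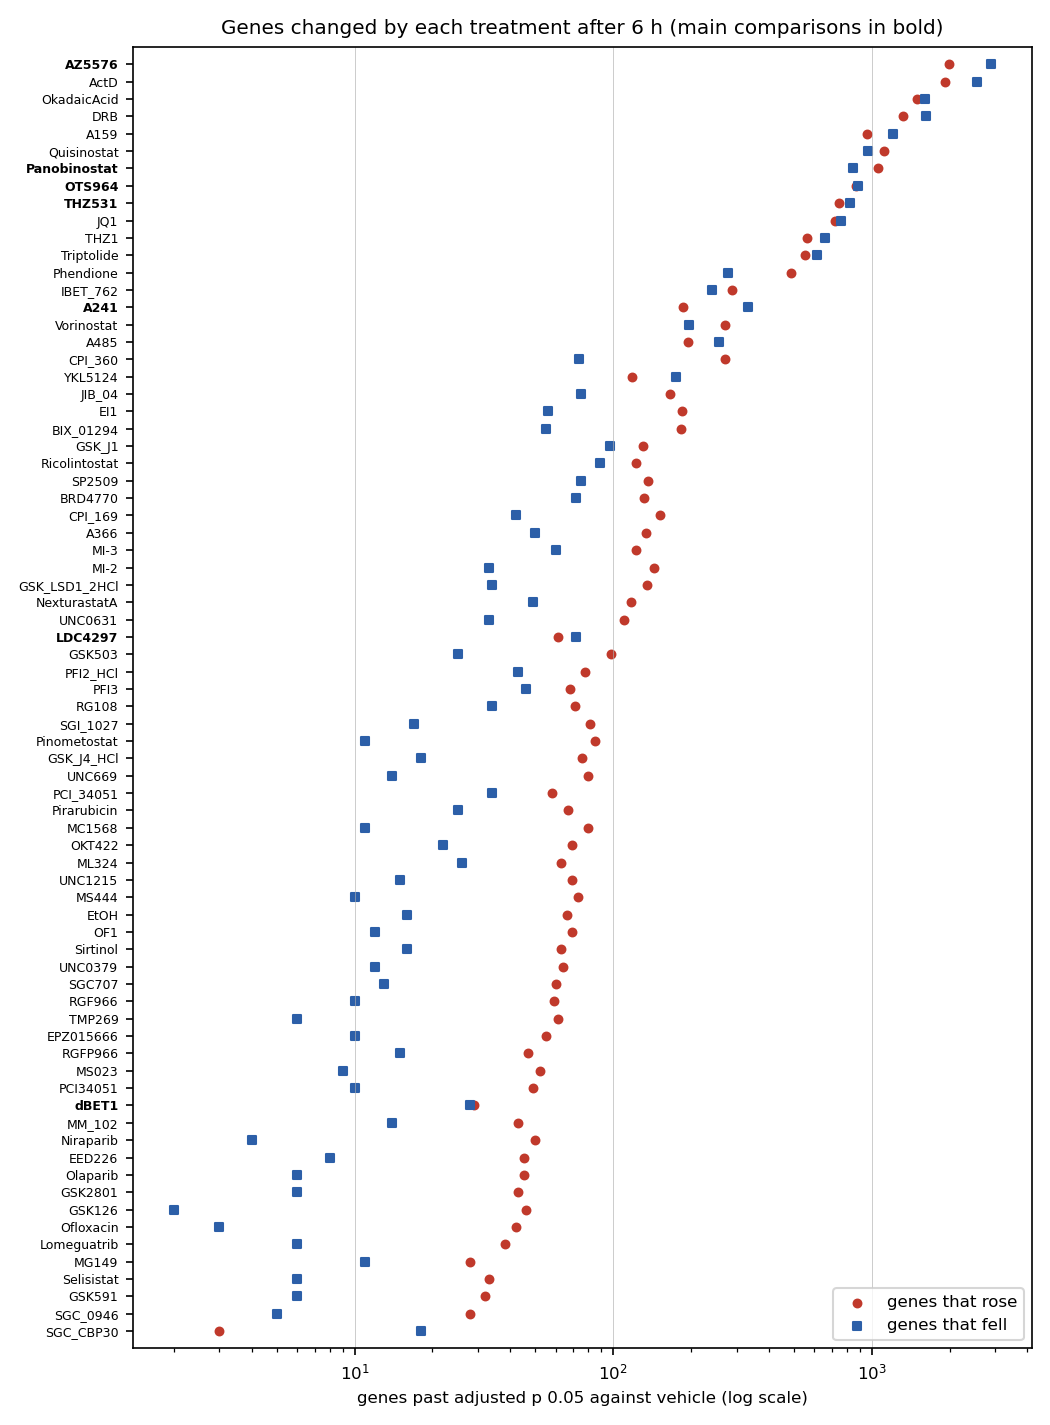
Number of genes past an adjusted p of 0.05 against DMSO for each of the 74 treatments, on a log scale; red circles are genes that rose, blue squares genes that fell, and the 7 main comparisons are in bold. Counts run from 21 genes for SGC_CBP30 to 4881 for AZ5576.

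AZ5576 inhibits CDK9, the kinase of P-TEFb that releases RNA polymerase II from pausing, an activity that was not measured here. The comparison shows which mRNAs were lower or higher, relative to the other genes, 6 h after AZ5576 was added. In its 6 wells 2896 genes fell and 1985 rose. Among the immediate early genes, which encode short-lived regulatory mRNAs, 23 of 34 fell and 0 rose (the same numbers adjusted over the list alone, median log2 fold change -1.78, camera adjusted p = 3.67e-08). They include MYC, a driver of cell growth (-2.82, SE 0.18), ID1, an inhibitor of helix-loop-helix factors (-2.68, SE 0.17), and ZFP36L2, an mRNA decay factor (-2.77, SE 0.31). Of the erythroid transcription factors 12 of 16 fell (12 adjusted over the list alone, median -1.45, camera adjusted p = 3.67e-08). KLF1, the activator of adult globin genes, stood at -2.46 (SE 0.15) and GFI1B, an erythroid repressor, at -2.26 (SE 0.22). The mRNAs these factors serve went the other way relative to the other genes: 18 of 31 erythroid effector genes rose and 2 fell (18 and 3 adjusted over the list alone, median 0.451, camera adjusted p = 3.4e-07), although the median turned to -0.31 with ERCC scaling. Embryonic HBZ was at 0.75 (SE 0.06) and fetal HBG2 at 0.61 (SE 0.05).

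Among the largest falls under AZ5576 of genes with a mean log2 CPM of at least 5 were those of MRPL17, a mitochondrial ribosomal protein (-3.53, SE 0.22, edgeR adjusted p = 9.1e-33), MAD2L1BP, which binds the checkpoint protein MAD2 (-3.43, SE 0.25), TNFRSF12A, the TWEAK receptor (-3.15, SE 0.22), and DNAJB1, an HSP40 chaperone (-2.92, SE 0.15, adjusted p = 7.8e-41). Stress regulators fell, 13 of 20 members of the integrated stress and unfolded protein list (13 adjusted over the list alone, median -0.738, camera adjusted p = 1.32e-05). Among them were DDIT3, a pro-apoptotic factor (-3.07, SE 0.29), and DDIT4, an inhibitor of mTORC1 signalling (-2.7, SE 0.23). The mitotic list had 17 of 24 genes lower (17 adjusted over the list alone, median -0.804, camera adjusted p = 0.000104), led by the kinase gene AURKA (-2.46, SE 0.24). Survival regulators fell in 8 of 13 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.539, camera adjusted p = 0.000529). PIM3, a survival kinase, was at -3.63 (SE 0.4) and MYB, a progenitor transcription factor, at -2.26 (SE 0.24). Of 25 P-TEFb and elongation genes 15 fell and 2 rose (16 and 2 adjusted over the list alone, median -0.841, camera adjusted p = 0.00572). BRD2, a BET protein, was at -2.53 (SE 0.27) and MEPCE, which caps 7SK RNA, at -2.36 (SE 0.28). Zinc finger genes named ZNF had 100 of 179 members lower and 3 higher (103 and 3 adjusted over the list alone, median -1.1, camera adjusted p = 8.04e-07), ZNF691 at -2.97 (SE 0.4) for example.

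Some lists were relatively higher under AZ5576. All 13 mitochondrial-encoded mRNAs, made by a separate polymerase, rose (13 adjusted over the list alone, median 0.714, camera adjusted p = 7.58e-24; MT-CO3 0.9, SE 0.06), with a median of -0.02 under ERCC scaling. Glycolytic genes rose in 9 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.229, camera adjusted p = 0.00234; LDHA 0.52, SE 0.05), a median that turned negative with library size alone (-0.11) and with ERCC scaling (-0.51). Interferon response genes rose in 4 of 10 cases and fell in 2 (4 and 2 adjusted over the list alone, camera adjusted p = 0.0143, direction up), but their median was 0.202 and their mean -0.036. The genes that rose include the membrane proteins IFITM1 (0.55, SE 0.06) and IFITM3 (0.53, SE 0.05). The median was -0.12 with library size alone and -0.54 with ERCC scaling. Ribosomal protein mRNAs rose in 70 of 80 cases (71 adjusted over the list alone, median 0.392, camera adjusted p = 2.84e-29, median -0.35 with ERCC scaling), a call lost at adjusted p = 0.054 with an estimated correlation. Lost in the same way were the falls of the deadenylation (adjusted p = 0.054 with an estimated correlation), splicing factor (0.171), snoRNA host (0.0563) and epigenetic target lists (0.187). With ERCC scaling the median of all genes shifted by -0.73, 40 genes rose and 8125 fell; with library size alone the shift was -0.31, 491 rose and 4711 fell. Single positions of the compound gave 2018, 3229 and 2341 genes, and the 3 positions differed from each other in 1 or 2 genes.

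LDC4297, an inhibitor of CDK7, the kinase of TFIIH, changed few genes in 2 wells: 61 rose and 72 fell. The clearest group was the hosts of small nucleolar RNAs, transcripts whose spliced form is degraded by nonsense-mediated decay: 8 of 12 fell (8 adjusted over the list alone, median -0.518, camera adjusted p = 1.01e-19). Among them were SNHG12 (-1.94, SE 0.28), SNHG1 (-1.04, SE 0.15) and GAS5 (-0.63, SE 0.08). Reads counted to the small nucleolar RNA gene SNORD104, which lies within its host SNHG25 (-1.71, SE 0.24) and can share its reads, fell most among genes with a mean log2 CPM of at least 5 and the same sign in both wells (-2.39, SE 0.36, edgeR adjusted p = 5.94e-07), and RABGGTB, a prenyltransferase subunit whose gene also hosts small nucleolar RNAs, fell as well (-1.35, SE 0.18). Genes that rose included JUNB, an AP-1 factor (0.93, SE 0.18, edgeR adjusted p = 0.000214), CFD, a complement protease (0.73, SE 0.12), and NFE2, a globin regulator (0.81, SE 0.12). DMSO wells themselves lay below 39 other compounds in NFE2 (difference -1.1), and against those compounds LDC4297 had NFE2 at -0.24.

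Mitotic genes moved down as a list under LDC4297, 2 of 24 past the threshold and 9 adjusted over the list alone (median -0.474, camera adjusted p = 3.16e-09), with AURKB at -0.75 (SE 0.13) and CDK1 at -0.53 (SE 0.15). Histone mRNAs did so too, 2 of 16 lower and 5 adjusted over the list alone (median -0.433, camera adjusted p = 0.000319). H2BC11 was at -0.72 (SE 0.12) and H4C3 at -0.8 (SE 0.16), whose level also depended on well position. Against the 39 other compounds, which lay below DMSO in H2BC11, the histone median was -0.2 with 1 of 16 lower. Mitochondrial-encoded mRNAs were higher in 5 of 13 cases and in 10 adjusted over the list alone (median 0.258, camera adjusted p = 4.48e-12; MT-ND3 0.43, SE 0.1, a gene that also differed between DMSO positions), but in 0 of 13 by edgeR against the 39 other compounds. Splicing factors were lower as a list with 1 member past the threshold, SRSF5 (-0.78, SE 0.21), and 3 adjusted over the list alone (median -0.296, camera adjusted p = 8.68e-05). Ribosomal proteins had a median of 0.104 (-0.03 with ERCC scaling) with 1 member lower (1 adjusted over the list alone), RPL10 at -0.42 (SE 0.1), and the call was lost at adjusted p = 0.646 with an estimated correlation. HNRNPH1 (-1.75, SE 0.44) and SNHG3 (-1.55, SE 0.21) also fell, but both differed between DMSO positions. With 1 of the 2 wells left out 19 or 21 genes were called, 29 in a fit of its wells and the DMSO wells alone, and ERCC scaling left 2 higher and 51 lower (median shift -0.15); library size alone gave 31 and 111.

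The other CDK7 compounds differed in reach. YKL5124 changed 293 genes and lowered the same kind of transcripts, with SNORD104 at -2.47 (SE 0.32), SNHG12 at -1.91 (SE 0.25) and 8 of 12 snoRNA hosts lower (9 adjusted over the list alone, median -0.481, camera adjusted p = 6.57e-19). LDC4297 and YKL5124 differed directly in 1 gene by edgeR, at a median 95% interval half-width of 0.79 and 473 genes at an unadjusted p under 0.05. That gene was TAOK1, a stress kinase, chosen after its value was seen (LDC4297 minus YKL5124 -6.43, SE 0.23, edgeR adjusted p = 5.21e-61). TAOK1 stood at 541 and 971 CPM in the YKL5124 wells of the 2 plates and at most at 28.7 in the other 190 wells (median 7.68). Both YKL5124 wells share 1 position and barcode, so an effect of the compound was not separated from one of the well. THZ1, which also binds CDK12 and CDK13, changed 1218 genes and differed from LDC4297 in 362 and from YKL5124 in 383. DNAJB1 was 4.66 higher in LDC4297 (SE 0.46) and MYC lower in THZ1 than in YKL5124 (difference -2.19, 95% interval -2.84 to -1.55). THZ1 and THZ531 differed in 69 genes, with ID1 at -3.31 (SE 0.4) and ZFP36L2 at -3.06 (SE 0.5) in THZ1 relative to THZ531, a pair chosen after the names were seen.

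THZ531, an inhibitor of CDK12 and CDK13, kinases needed for elongation through long genes, raised immediate early genes in its 2 wells while lowering erythroid regulators. Of the 34 immediate early genes 12 rose and 1 fell (14 and 2 adjusted over the list alone, median 0.889, camera adjusted p = 4.58e-14). With ERCC scaling, which rests on all DMSO wells with the first column included, the median was 0.07, and 9 rose and 8 fell. With TMM scaling IER2 rose by 3.44 (SE 0.12, edgeR adjusted p = 9.47e-63), IER3, an anti-apoptotic response gene, by 3.54 (SE 0.21), the AP-1 factor JUNB by 3.24 (SE 0.14) and HES1, a Notch target, by 2.3 (SE 0.27). Erythroid transcription factors fell in 8 of 16 cases and rose in 1 (8 and 1 adjusted over the list alone, median -1.71, camera adjusted p = 1.78e-05). GFI1B was at -2.71 (SE 0.45), NFE2 at -2.09 (SE 0.28) and KLF1 at -1.95 (SE 0.25). Erythroid effectors were higher in 10 of 31 cases (11 higher and 1 lower adjusted over the list alone, median 0.252, camera adjusted p = 0.000256; HBA1 0.65, SE 0.11), with a median of -0.57 under ERCC scaling. In all, 750 genes rose and 821 fell.

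Among the largest falls under THZ531, with the same limit, were RELL2 (-4.53, SE 0.82, edgeR adjusted p = 8.54e-06), NFKBIL1 (-3.7, SE 0.56), LMO2, a blood progenitor factor (-3.52, SE 0.87, not called by DESeq2), and the ribosome assembly genes SURF6 (-3.39, SE 0.64) and PPAN (-3.3, SE 0.66). These genes stood at 1.403 (LMO2) to 2.964 CPM (SURF6 and PPAN) in the THZ531 wells, which held 418108 and 358938 human counts. The sizes of these falls thus rest on very few reads and are uncertain. Mitotic genes fell in 8 of 24 cases (8 adjusted over the list alone, median -0.592, camera adjusted p = 0.000265; the centromere histone CENPA -2.33, SE 0.49). Stress genes fell in 6 of 20 cases (8 lower and 1 higher adjusted over the list alone, median -0.624, camera adjusted p = 0.000256; DDIT3 -2.33, SE 0.49; XBP1 -1.65, SE 0.43). Survival regulators fell in 4 of 13 (6 adjusted over the list alone, median -0.536, camera adjusted p = 0.00935; MYB -1.91, SE 0.42). ZNF genes fell in 22 of 179 cases and rose in 1 (16 and 1 adjusted over the list alone, median -0.911, camera adjusted p = 0.000289). Heat shock genes rose in 4 of 18 cases and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0313; HSPA1B 1.36, SE 0.27, against DNAJB1 -1.87, SE 0.24), a call lost at adjusted p = 0.102 with an estimated correlation. Relatively higher were 12 of 13 mitochondrial-encoded mRNAs (13 adjusted over the list alone, median 0.397, camera adjusted p = 3.22e-15) and 4 of 17 glycolytic genes (6 higher and 2 lower adjusted over the list alone, median 0.159, camera adjusted p = 0.00122; GAPDH 0.83, SE 0.09). So were 3 of 10 interferon genes (3 adjusted over the list alone, median 0.395, camera adjusted p = 0.0173; ISG15 0.83, SE 0.2) and 39 of 80 ribosomal protein mRNAs (54 adjusted over the list alone, median 0.316), the last lost at adjusted p = 0.105 with an estimated correlation. With ERCC scaling these 4 medians and that of the heat shock list turned negative (-0.4, -0.64, -0.4, -0.49 and -0.67), as the median of all genes shifted by -0.82 and 42 genes rose against 5587 that fell. Library size alone (shift -0.23) gave 224 and 1268 and turned the glycolytic and heat shock medians to -0.07. Without 1 of the wells 446 or 463 genes were called.

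OTS964, an inhibitor of CDK11, a kinase tied to splicing and to histone mRNA synthesis, raised 872 genes and lowered 888 in 2 wells. Among the largest falls, with the same limit, were those of the microRNA host transcripts MIR23AHG (-3.15, SE 0.6) and MIR17HG (-3.12, SE 0.5), and of JAGN1, an endoplasmic reticulum protein (-2.64, SE 0.26, edgeR adjusted p = 8.23e-16). BRD2 rose (1.28, SE 0.2), as did MAD2L1BP (1.33, SE 0.15, edgeR adjusted p = 3.13e-12), the nuclear RNA MALAT1 (1.19, SE 0.2), SRRM1, a splicing coactivator (1.01, SE 0.2), and MSMO1, an enzyme of cholesterol synthesis (1.13, SE 0.21). Erythroid effectors rose in 10 of 31 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.284, camera adjusted p = 3e-04; HBG1 0.57, SE 0.07; HBA2 0.63, SE 0.11), and 12 of 13 mitochondrial-encoded mRNAs rose (13 adjusted over the list alone, median 0.455, camera adjusted p = 3.15e-14; MT-ND5 0.63, SE 0.09); with ERCC scaling the medians were -0.47 and -0.29.

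Other list calls under OTS964 depended on the correlation between genes. Ribosomal protein mRNAs rose in 55 of 80 cases (69 adjusted over the list alone, median 0.377, -0.37 with ERCC scaling; RPL29 0.54, SE 0.07; adjusted p = 0.124 with an estimated correlation). Erythroid transcription factors fell in 5 of 16 cases (5 lower and 1 higher adjusted over the list alone, median -0.505; KLF1 -1.26, SE 0.19; adjusted p = 0.155 with an estimated correlation). Against the 39 other compounds, which lay above DMSO in these factors, the median was -1.11 with 9 of 16 lower. The snoRNA hosts fell in 5 of 12 cases (5 adjusted over the list alone, median -0.233; SNHG12 -1.9, SE 0.32; adjusted p = 0.124 with an estimated correlation). ZNF genes fell in 24 of 179 cases while 4 rose (22 and 4 adjusted over the list alone, median -0.4; adjusted p = 0.155 with an estimated correlation). Their camera adjusted p with the preset correlation were 2.8e-31, 0.0127, 0.00949 and 0.0285. The histone list (median -0.01) and the splicing factor list (median -0.11) were not among the 6 lists called for OTS964. With ERCC scaling the median of all genes shifted by -0.75, and 25 genes rose against 5469 that fell; library size alone gave a shift of -0.24, 184 rises and 1537 falls. Without 1 of the wells 586 or 654 genes were called.

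dBET1, a degrader of BET bromodomain proteins, changed the fewest genes of the main comparisons, 29 higher and 28 lower in 2 wells. PIM1, a survival kinase, fell (-0.99, SE 0.15, edgeR adjusted p = 1.7e-06), as did MYC (-0.56, SE 0.14, adjusted p = 0.0296). In all, 2 of 13 survival regulators fell (4 adjusted over the list alone, median -0.205, camera adjusted p = 0.000159). Against the 39 other compounds the median was -0.47 with 6 of 13 lower. NFE2 rose against DMSO (0.63, SE 0.11) but stood at -0.43 with the 39 other compounds as reference. The stress list was lower with SLC3A2, an amino acid transporter chain (-0.6, SE 0.15), and ATF4, its regulator (-0.61, SE 0.16), past the threshold (2 of 20; 6 lower and 1 higher adjusted over the list alone, median -0.236, camera adjusted p = 0.0128). Histone mRNAs were higher as a list with 0 of 16 past the threshold over all genes and 5 adjusted over the list alone (median 0.156, camera adjusted p = 0.00375).

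For dBET1 10 further list calls were lost with an estimated correlation, among them immediate early (adjusted p = 0.0593 with an estimated correlation), erythroid effector (0.0736; HBG1 0.33, SE 0.08; median 0.069, mean 0, and -0.05 with library size alone), mitotic (0.0736; AURKB -0.5, SE 0.11) and ribosomal protein lists (0.0825; 0 of 80 past the threshold and 56 adjusted over the list alone, median 0.25). Several of the largest falls, HNRNPH1 (-1.92, SE 0.42), WTAP (-1.38, SE 0.29), TRA2A (-1.25, SE 0.3), SPC24 (-1.24, SE 0.27) and TOR1AIP2 (-1.2, SE 0.26), are genes that also differed between DMSO positions. The count rested on both wells: without 1 of them 0 or 2 genes were called by edgeR (787 or 1246 at an unadjusted p under 0.05). It was 2 in a fit with the DMSO wells alone and 1 with ERCC scaling (1 higher, 0 lower, median shift 0.11). Size factors gave 22 higher and 49 lower, library size alone 8 and 105 (shift -0.11), limma-voom 160 genes and DESeq2 109. Single DMSO wells mattered too: without DMSO replicates 6, 9, 18 or 22 it was 88, 108, 91 or 89.

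The BET bromodomain inhibitors JQ1 (6 wells) and IBET_762 (4 wells) changed 1484 and 528 genes. With 2 wells, as for dBET1, single positions gave 1486, 631 and 358 genes for JQ1 and 274 and 183 for IBET_762. JQ1 raised 14 of 16 histone genes (14 adjusted over the list alone, median 1.51, camera adjusted p = 3.91e-67) and HEXIM1, an inhibitor of P-TEFb (1.63), and lowered LMO2 (-2.25, SE 0.36) and HEMGN, a haematopoietic nuclear protein (-2.17, SE 0.29). IBET_762 raised 11 of 16 histone genes (12 adjusted over the list alone, median 1.01, camera adjusted p = 2.85e-61) and lowered HEMGN (-1.46, SE 0.23). dBET1 differed from JQ1 in 614 genes and from IBET_762 in 155, while IBET_762 and JQ1 differed in 194. Of the 6 JQ1 wells 4 lie in the first column, and those of dBET1 and IBET_762 lie in other columns. Contrasts with JQ1 therefore mix compound and column, and first-column DMSO wells differed from the other DMSO wells in 2332 genes. HEXIM1 was lower in dBET1 than in JQ1 (difference -2.72, 95% interval -3.32 to -2.12) and GATA1, the erythroid master regulator, 0.99 higher (0.7 to 1.27), whereas the difference in MYC was 0.01 (-0.35 to 0.37). JQ1 positions were not alike: well 22 differed from wells 49 and 61, both in the first column, in 620 and 323 genes. Against DMSO HEXIM1 stood at 1.02, 2.46 and 1.73 in wells 22, 49 and 61, and GATA1 at -1.01, -0.55 and -0.26. Within the first column and outside it the compound changed 695 and 1089 genes against the DMSO wells of the same part, 420 of them in both and in the same direction.

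A241, an inhibitor of the acetyltransferases CBP and p300, lowered erythroid transcription factors, the list with the lowest median among those called for it. In its 2 wells 187 genes rose and 332 fell. Of 16 erythroid transcription factors 8 fell (11 adjusted over the list alone, median -1.88, camera adjusted p = 4.69e-30). These include GFI1B (-3.69, SE 0.43), KLF1 (-2.99, SE 0.25, edgeR adjusted p = 2.52e-20), LYL1, a progenitor factor (-2.85, SE 0.33), and GATA1 (-2.58, SE 0.22, adjusted p = 2.96e-20). Erythroid effectors fell in 8 of 31 cases (12 lower and 1 higher adjusted over the list alone, median -0.432, camera adjusted p = 2.19e-10). Among them were the haem synthesis enzyme UROD (-0.63, SE 0.08) and the transferrin receptor TFRC (-1.49, SE 0.24). Survival regulators fell in 7 of 13 cases (9 adjusted over the list alone, median -0.972, camera adjusted p = 7.1e-14). PIM2 was at -2.7 (SE 0.33), MYC at -2.03 (SE 0.24) and the cyclin CCND3 at -1.16 (SE 0.14).

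Metabolic lists also fell under A241. Cholesterol synthesis genes fell in 6 of 19 cases (6 adjusted over the list alone, median -0.448, camera adjusted p = 1.05e-07), with INSIG1, a sterol sensor partner (-1.48, SE 0.2), and SQLE, squalene epoxidase (-1.52, SE 0.32). Glycolytic genes fell in 6 of 17 cases (9 adjusted over the list alone, median -0.263, camera adjusted p = 4.54e-06), with PKM, pyruvate kinase (-0.73, SE 0.12), and the glucose transporter SLC2A1 (-1.22, SE 0.27). Immediate early genes fell in 10 of 34 cases and rose in 1 (13 and 1 adjusted over the list alone, median -0.864, camera adjusted p = 1.05e-07; ID1 -2.67, SE 0.26). Ribosome biogenesis genes fell in 5 of 37 (6 adjusted over the list alone, median -0.331, camera adjusted p = 1.58e-06; NOP16 -0.89, SE 0.12), and snoRNA hosts in 3 of 12 (4 adjusted over the list alone, median -0.18, camera adjusted p = 1.01e-05; SNHG15 -1.19, SE 0.21). Histone genes fell in 2 of 16 (2 adjusted over the list alone, median -0.346, camera adjusted p = 0.0058; H2AC6 -0.82, SE 0.15). Stress genes fell in 4 of 20 cases (6 adjusted over the list alone, median -0.077, camera adjusted p = 0.0377; DDIT4 -2.72, SE 0.36), and heat shock genes in 4 of 18 (5 adjusted over the list alone, adjusted p = 0.0666 with an estimated correlation). Mitotic genes went up, 5 of 24 past the threshold (10 adjusted over the list alone, median 0.343, camera adjusted p = 1.86e-07; CENPE, a kinetochore motor, 1.34, SE 0.38; CDK1 0.52, SE 0.13). Replication genes had a median of 0.192 with 0 of 27 past the threshold over all genes or over the list alone (camera adjusted p = 0.00819). No median of a called list changed sign with another scaling, but ERCC scaling left 49 higher and 164 lower genes. With it 0 of 24 mitotic genes were called higher, CDK1 and CENPE included, while the median of that list was 0.3. Without 1 of the wells 117 or 129 genes were called, and 303 in a fit with the DMSO wells alone. Against the other compounds as reference 949 were, 469 of them called in the same direction against DMSO.

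A485, a catalytic inhibitor of CBP and p300, changed 451 genes. Among those with a mean log2 CPM of at least 5 and the same sign in every treated well, GFI1B (-1.68, SE 0.19), KLF1 (-1.59, SE 0.12) and DDIT4 (-1.48, SE 0.18) were lowest. A241 and A485 differed in 34 genes, 33 of them lower in A241, including GATA1 (difference -1.8, 95% interval -2.3 to -1.3) and MYC (-1.39, -1.95 to -0.84). SGC_CBP30, which binds the bromodomains of the same proteins, differed from DMSO in 21 genes. It differed from A241 in 368, with GFI1B lower in A241 (-3.92, SE 0.47), and from A485 in 373. Its wells lay below 39 other compounds in the mean of LMO2, KLF1, NFE2 and LYL1 (-0.71 and -0.521), on the same side as DMSO (-1.014). The count of 21 therefore does not measure its activity. Contrasts of A485 with A241 and with SGC_CBP30, whose wells lie in other columns, mix compound and column. Of the 6 wells of A485, 4 lie in the first column (positions 25 and 37). Position 33 differed from them in 266 and 313 genes, while 25 and 37 differed in 0 by edgeR (503 at an unadjusted p under 0.05). Within it and outside it 75 and 193 genes changed against DMSO wells of the same part, 40 in both and in the same direction, with KLF1 at -1.31 and -1.7.

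Panobinostat, an inhibitor of histone deacetylases, raised 1062 genes and lowered 844 in 2 wells. Histone genes rose in 9 of 16 cases (11 adjusted over the list alone, median 0.918, camera adjusted p = 1.21e-15). H3C4 was at 2.65 (SE 0.19) and H2BC5 at 2.24 (SE 0.15). Erythroid transcription factors fell in 13 of 16 cases (13 adjusted over the list alone, median -1.59, camera adjusted p = 1.21e-15). NFE2 was at -2.46 (SE 0.22), KLF1 at -1.9 (SE 0.19) and MYB at -2.76 (SE 0.35). Among the genes with a mean log2 CPM of at least 5 that rose most were NEU1, a lysosomal sialidase (2.77, SE 0.13, edgeR adjusted p = 2.99e-44), DNAJB1 (2.52, SE 0.08, adjusted p = 5.44e-66), SAT1, the polyamine acetyltransferase (2.36, SE 0.13), and the tubulin gene TUBB2A (2.2, SE 0.16). With that limit the one that fell most was HOXB2, a homeobox gene (-3.54, SE 0.34). Cholesterol synthesis genes rose in 10 of 19 cases (10 higher and 1 lower adjusted over the list alone, median 0.393, camera adjusted p = 3.69e-07). INSIG1 rose by 1.85 (SE 0.1) and IDI1, an isoprenoid isomerase, by 1.55 (SE 0.09).

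Other lists moved under Panobinostat too. Immediate early genes rose in 18 of 34 cases and fell in 6 (19 and 6 adjusted over the list alone, median 1, camera adjusted p = 5.58e-07; GADD45B, a stress sensor, 4.39, SE 0.39; ID2 3.27, SE 0.28). Heat shock genes rose in 6 of 18 cases (6 adjusted over the list alone, median 0.085, and -0.03 with ERCC scaling, camera adjusted p = 4.43e-06; HSPA1A 1.99, SE 0.11; HSP90AA1 1.15, SE 0.11). The 6 genes listed as reporters of BET inhibition rose in 5 cases (6 adjusted over the list alone, median 1.76, camera adjusted p = 1.55e-12); they include histone genes such as H2BC21 (2, SE 0.22). Interferon response genes rose in 5 of 10 cases (5 adjusted over the list alone, median 0.191, camera adjusted p = 0.0076; IFI6 3.48, SE 0.47). Survival regulators fell in 5 of 13 cases and rose in 1 (6 and 1 adjusted over the list alone, median -0.683, camera adjusted p = 0.000233; BCL2L1, an anti-apoptotic gene, -1.42, SE 0.24). Splicing factors fell in 7 of 21 (8 adjusted over the list alone, median -0.375, camera adjusted p = 0.000185; SRSF4 -1.4, SE 0.21) and snoRNA hosts in 5 of 12 (6 adjusted over the list alone, median -0.207, camera adjusted p = 0.000371; SNHG8 -1, SE 0.14). ZNF genes had 23 of 179 lower and 8 higher (21 and 8 adjusted over the list alone, adjusted p = 0.0746 with an estimated correlation). The nuclear exosome list passed with an estimated correlation alone (camera adjusted p = 0.0564, adjusted p = 0.0482 with an estimated correlation). ERCC scaling gave 503 higher and 789 lower genes (median shift -0.13), and without 1 of the wells 901 or 949 were called.

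Among the HDAC compounds Quisinostat differed from Panobinostat in 1 gene, CIRBP, a cold-induced RNA-binding protein named after its value was seen (0.88 higher in Panobinostat, SE 0.12), at a median 95% interval half-width of 0.79 and 377 genes at an unadjusted p under 0.05. Vorinostat changed 468 genes and differed from Panobinostat in 115, with NEU1 1.8 higher (SE 0.23) and NFE2 lower (difference -2.5, SE 0.29) in Panobinostat. PCI_34051, PCI34051 and RGFP966, compounds directed at single HDAC enzymes, differed from DMSO in 92, 59 and 62 genes and from Panobinostat in 1127, 985 and 979. EtOH and EED226 differed from DMSO in 82 and 53 genes but from 39 other compounds in 0. Counts of this size against DMSO therefore need not reflect the compound. The wells named PCI_34051 and PCI34051 differed in 0 genes by edgeR (419 at an unadjusted p under 0.05, half-width 0.83), and those named RGF966 and RGFP966 in 6.

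**Figure D2:**
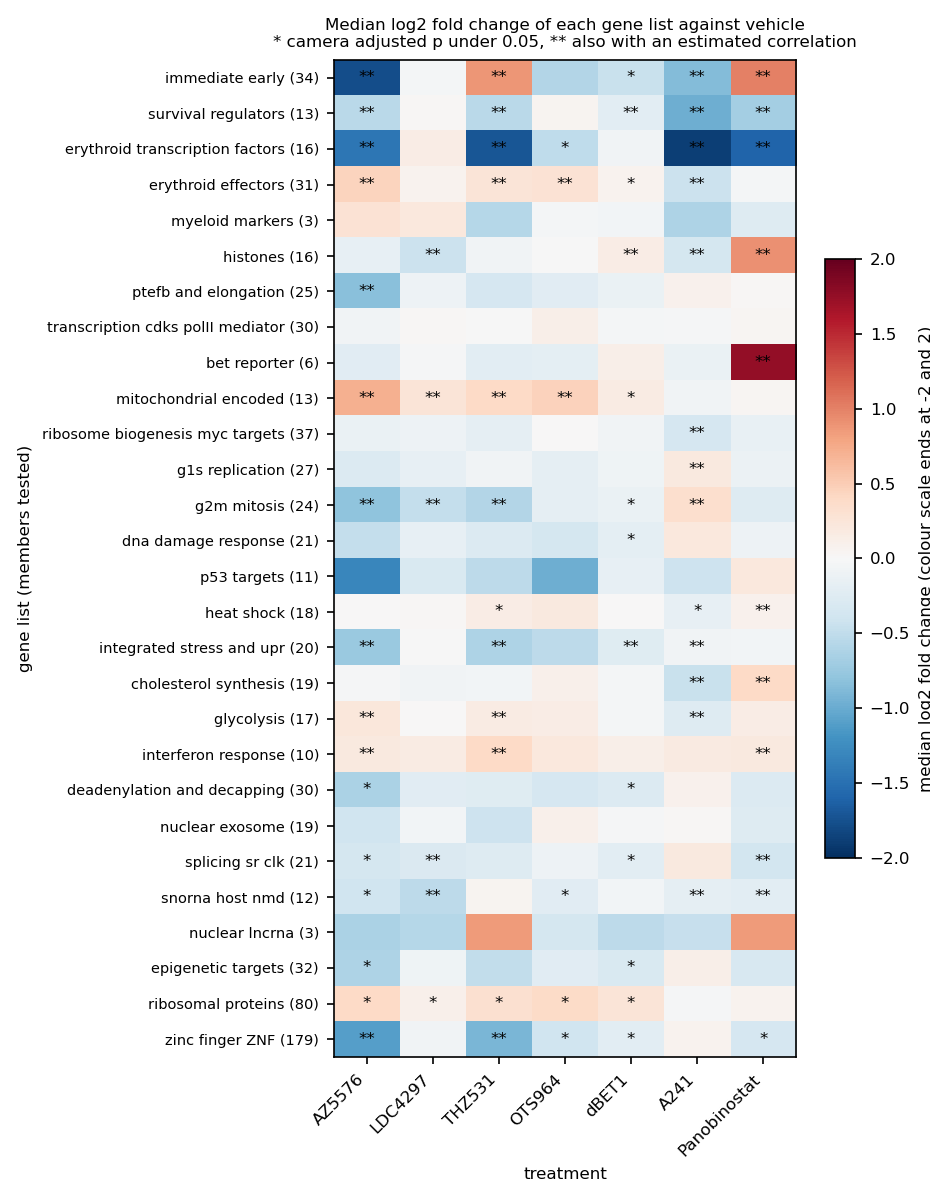
Median log2 fold change against DMSO of each of the 28 gene lists (vertical axis, members tested in brackets) in the 7 main comparisons (horizontal axis), as colour from blue (lower) to red (higher), with TMM scaling. One star marks a camera adjusted p under 0.05, and a pair of stars marks lists that also pass with an estimated correlation; medians above 0 in AZ5576, THZ531 and OTS964 turned negative with ERCC scaling, except those of the immediate early (0.07) and nuclear lncRNA lists (0) in THZ531.

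The lookup genes show how common some changes were against DMSO. MYC fell in 12 treatments (lowest -2.82, AZ5576) and rose in 49 (highest 0.86, UNC0631), and GATA1 fell in 6 (lowest -2.58, A241) and rose in 52 (highest 1.24, UNC0631). The erythroid transcription factor list was called up in 52 treatments and down in 14. DMSO wells outside the first column themselves lay below 39 other compounds in MYC (-0.64) and GATA1 (-0.94), which bears on these rises. HEXIM1 rose in 5 treatments, most in JQ1, and fell in 5, most in DRB (-1.64). FOS, an AP-1 factor, rose in 5 treatments, most in OkadaicAcid (6.98, SE 0.31), and fetal HBG1 in 23, most in AZ5576 (0.6, SE 0.05). With ERCC scaling the HBG1 value of AZ5576 turned negative. GAPDH, often used as a control gene, rose in 13 treatments, most in THZ531 (0.83, SE 0.09), and fell in 6, and with ERCC scaling it stood at -0.23 in AZ5576.

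The human to ERCC ratio, a measure of RNA per well that joins cell number, lysis and RNA per cell, was lower in ActD alone past adjustment: its 6 wells held 61.5% of the vehicle ratio (log2 difference -0.7, lower in 6 of 6 wells, two-sided exact permutation p = 2.42e-05, adjusted p = 0.00179). AZ5576 was at 76.4% (-0.39, lower in 6 of 6 wells, exact p = 0.0054, adjusted p = 0.146), THZ531 at 69% (-0.53, exact p = 0.0237, adjusted p = 0.292) and OTS964 at 72.7% (-0.46, exact p = 0.0414, adjusted p = 0.365), each lower in both wells where there were 2. With 2 wells the smallest possible exact p is 0.00592, so a treatment with 2 wells could not pass alone after adjustment over 74. LDC4297 (-0.01), A241 (-0.04) and Panobinostat (0) lay within the SD of the vehicle wells, 0.287 and 0.304 on the plates, and dBET1 was at 0.29 (exact p = 0.195). The 8 first-column DMSO wells all lay below their plate's vehicle mean (highest -0.19 and -0.2). Without the first column AZ5576 passed as well (-0.56, exact p = 3.67e-05, adjusted p = 0.00136), as did ActD (-0.87, the same p, the smallest possible). The other main comparisons moved down as well: THZ531 to -0.7 and OTS964 to -0.63 (exact p = 0.0123 each, the smallest possible for 2 wells, adjusted p = 0.102), A241 to -0.21, LDC4297 to -0.17, Panobinostat to -0.16 and dBET1 to 0.12. Values of genes and lists with ERCC scaling also rest on all DMSO wells and were not refitted without the first column. The sign of medians near 0 with that scaling is therefore uncertain. Examples are the immediate early genes in THZ531 (0.07) and the mitochondrial-encoded mRNAs in AZ5576 (-0.02).

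**Figure D3:**
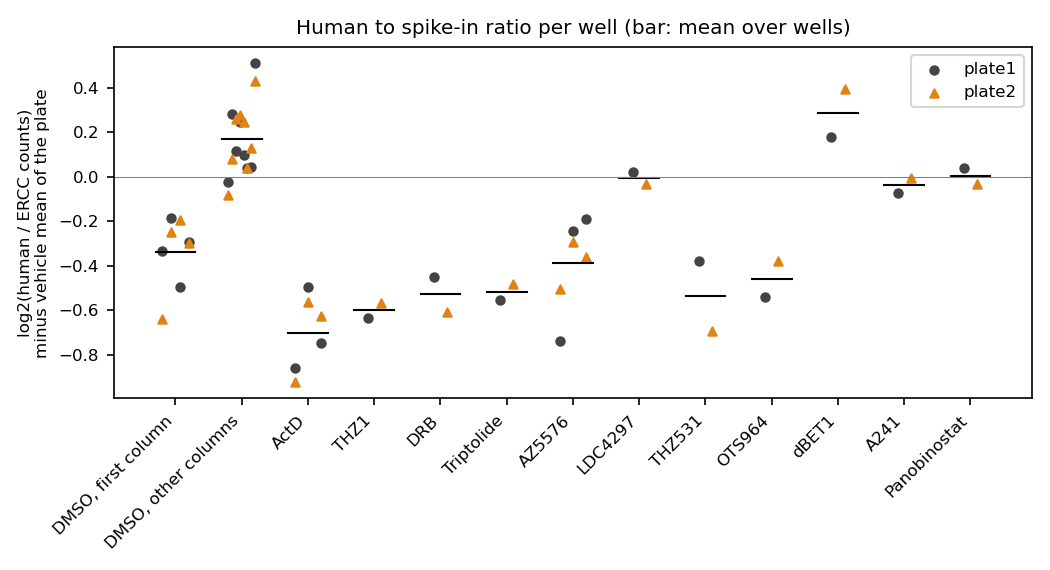
Log2 ratio of human to ERCC counts in single wells minus the DMSO mean of the plate (vertical axis), for DMSO wells of the first and other columns and 11 treatments (horizontal axis); circles are plate 1, triangles plate 2 and bars the mean. ActD wells lie lowest (mean -0.7), and the first-column DMSO wells lie below the other DMSO wells.

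Similarity of responses was measured as the correlation of log2 fold changes across genes, which are not independent replicates. Over the 21 pairs of main comparisons the median r was 0.176 (-0.056 to 0.535). It was 0.33 among genes with a mean log2 CPM of at least 5, and 0.156 with the DMSO wells split between the comparisons. Simulated unchanged groups sharing the DMSO wells gave 0.071 with 2 wells each. Groups simulated as unchanged from DMSO leave out the offset of the DMSO wells described below. EtOH differed from 39 other compounds in 0 genes, and Ofloxacin is among those compounds. Against DMSO this pair had r = 0.284 (0.214 with the DMSO wells split, covariance minus simulated 0.0394). Values of r near that size therefore need not reflect the compounds. AZ5576 resembled DRB (r = 0.725, simulated 0.078, covariance minus simulated 0.754) and ActD (0.724, simulated 0.148, covariance 0.539, simulated 0.0127) most. With DRB, 1155 genes rose and 1393 fell in both, where independent lists would share 255.1 and 454.1. Its r with THZ531 was 0.535 (covariance minus simulated 0.574; 624 and 708 shared against 144.4 and 230.6), with OTS964 0.416 (0.333; 717 and 689 against 167.9 and 249.4), with dBET1 0.424 (0.145; 21 and 21 against 5.6 and 7.9) and with A241 -0.051 (-0.0459; 13 and 132 against 36 and 93.2). dBET1 had a lower r with the BET inhibitors JQ1 (0.226, simulated 0.078) and IBET_762 (0.304). AZ5576 and DRB differed directly in 12 genes, with HSPA8 0.72 higher (SE 0.12) and MSMO1 lower (-1.71, SE 0.32) in AZ5576. A241 and A485 had r = 0.409 (simulated 0.078, covariance minus simulated 0.082; 43 and 127 shared against 3.5 and 8.3). Panobinostat and Quisinostat had 0.762 (0.071, 0.416; 786 and 565 against 115.1 and 78.8). LDC4297 and YKL5124 had r = 0.355 (0.071, 0.0555; 16 and 42 against 0.7 and 1.2).

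The DMSO wells themselves differed from the body of the compounds. Against 78 wells of 39 compounds outside the main classes, the 16 DMSO wells outside the first column were higher in 861 genes and lower in 1011 by edgeR. Erythroid transcription factors were lower in 11 of 16 cases (11 adjusted over the list alone, median -0.538, camera adjusted p = 3.32e-28), with LMO2 at -1.38 (SE 0.1), NFE2 at -1.1 (SE 0.05), LYL1 at -0.95 (SE 0.06) and GATA1 at -0.94 (SE 0.05). MYC was also lower (-0.64, SE 0.05), while HEXIM1 (0.49, SE 0.12) and the histone gene H2BC11 (0.52, SE 0.04) were higher. The EtOH wells, and those of EED226 and GSK126, differed from these compounds in 0 genes by edgeR (482, 538 and 442 at an unadjusted p under 0.05) but from DMSO in 82, 53 and 48. Rises of these factors and of MYC over DMSO, in 52 treatments for GATA1 and 49 for MYC, are therefore given against a vehicle that lay below these compounds on average. Counts against the 39 compounds were 4955 for AZ5576, 121 for LDC4297, 1377 for THZ531, 1667 for OTS964, 108 for dBET1, 949 for A241 and 2111 for Panobinostat, of which 4288, 64, 1176, 1372, 14, 469 and 1639 were also called against DMSO in the same direction.

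**Figure D4:**
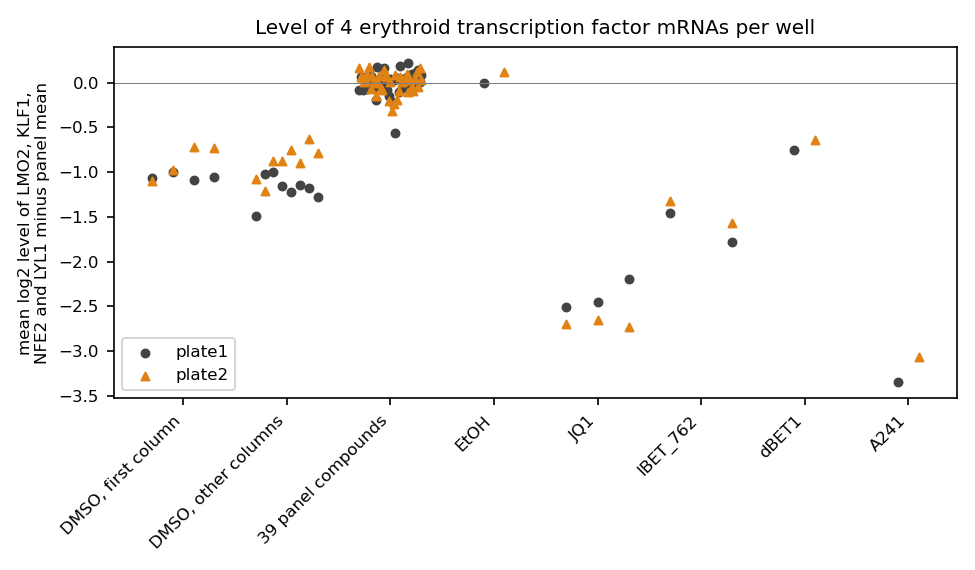
Mean log2 level of LMO2, KLF1, NFE2 and LYL1 in single wells minus the mean of the 39 panel compounds (vertical axis) for DMSO wells, panel wells, EtOH and compounds of the BET and CBP classes (horizontal axis); circles are plate 1 and triangles plate 2. All 24 DMSO wells lie between -1.49 and -0.63, the EtOH wells near 0 and the JQ1 wells between -2.73 and -2.2.

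Level also depended on the well. Between the 8 DMSO positions outside the first column 89 genes differed, with the plates as replicates, and over all 12 positions 1327. HNRNPH1, a splicing regulator, ranged from -1.35 to 1.12 between the 8 DMSO positions. Over 39 positions of panel compounds it had r = 0.979 between the plates (Spearman's rho 0.968, permutation p = 1e-05 for r, the smallest possible). Panel positions hold the same compound on both plates, so this r does not separate position from compound, as the DMSO positions do. Direct contrasts of compounds with a shared target in other classes gave few genes: 0 for Pinometostat and SGC_0946 (DOT1L, 413 at an unadjusted p under 0.05), 0 for EPZ015666 and GSK591 (PRMT5, 293), 0 for EED226 and GSK126 (PRC2, 329) and 0 for A366 and BIX_01294 (G9a, 439), all by edgeR with interval half-widths of 0.72 to 0.89. GSK_LSD1_2HCl and SP2509, named as LSD1 inhibitors and paired after the names were seen, differed in 8 genes, with GFI1B 1.76 higher (SE 0.19) in the former.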

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

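Chosen after the result was seen were the tests of vehicle wells outside the first column, of the column block and of the EtOH wells for the erythroid factors, and both tests of the first-column wells; the LMO2, KLF1, NFE2 and LYL1 set was itself picked from the data.

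In AZ5576 1 of 6 wells, on plate 1 in column 11, stood apart in GAPDH (0.47 against 0.54 to 0.57 in the others, log2 from the vehicle mean), and in GSK503 1 of 4 wells, on plate 1 in column 11, stood apart in FOS (0.16 against -0.27 to -0.21). These are 2 of 66 tests (6 groups, 11 measures), and chance sets apart about 1 in 20 such groups. No biological explanation was tested for either.

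Wells named DMSO lay below the 39 panel compounds in LMO2, KLF1, NFE2 and LYL1. Low depth of the first column is not the whole cause, since the panel stood 1.04 above the DMSO wells of the other columns. Scaling is not either, with 1.11 under ERCC scaling, nor is the block of columns of the panel, with EED226 and GSK126, which lie elsewhere, 1 above DMSO. EtOH wells stood 1.07 above DMSO, so a candidate explanation is the solvent of the DMSO wells, in kind or amount; amounts are not given, and other differences in how the DMSO wells were handled stay open.

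Some genes, HNRNPH1 first, differed between vehicle positions in the same way on both plates. Chance agreement of the plates is excluded as the cause, as 1 of 80 pairings of positions, the real one, gave as many genes (89, against at most 59), and these 89 genes lie outside the low depth of the first column. The number of A bases in the well barcode went with HNRNPH1 across panel positions (absolute r 0.57), which is consistent with an effect of the barcode on priming or counting. Place on the plate goes with the barcode on both plates, and over panel positions the compound does too. Other effects of place stay open, as does the compound for the correlation over panel positions, and no biological explanation was tested.

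Wells of the first column had fewer counts and a lower human to ERCC ratio. The treatments in that column are excluded as the cause, as all 8 of its DMSO wells lay under the median of the other DMSO wells of their plate. Fewer cells or less RNA alone would leave the ERCC species in the same proportions, but first-column and other DMSO wells differed 4.59 times as much in them (chi-square per degree of freedom 8.26) as the other DMSO wells among themselves (1.8), as medians over pairs. On plate 1 the ranges were apart (5.3 to 10.27 against 0.68 to 3.27), and on plate 2 they overlapped (5.32 to 13.21 against 0.89 to 12.51). Of the 495 choices of 4 DMSO wells none but the first column gave as high a ratio on either plate (one-sided exact permutation p = 0.00202 each, the smallest possible). What changed in the reaction stays open, and no biological explanation was tested.

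For comparisons with at least 3 wells per group, 100 splits of treated and vehicle wells were counted, the real one included. Only the real split (1 split) gave as many genes for AZ5576 (4881 genes, highest other 1214) and ActD (4457, highest other 1884). The same held for JQ1 (1484, highest other 753), IBET_762 (528, highest other 134) and A485 (451, highest other 254). Random splits of this kind thus did not reach these counts. They moved wells within each plate and did not keep a position shared by both plates. They therefore cannot tell a compound from its well positions, such as the first-column wells of A485 and JQ1. For GSK503, 2 splits gave as many as the real 123 genes, and the other, with 514, put 3 first-column wells in the treated group, which points to that column as a structure of the wells. The highest other splits of A485 and JQ1 held 5 first-column wells each, and that of ActD shared 4 of its treated wells.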

How the results depend on the processing

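Taking the panel compounds as reference, leaving out the first column and splitting by position were chosen after the result was seen, as was the pairing of DMSO wells by position. No paired analysis was possible because each well position holds 1 treatment and nothing links treated to DMSO wells except the plate, which is a term of the model. A replicate block was not run, as the annotation gives no replicate number. Minima of 50000 counts or none removed no well. Where no cause is given, the cause was not tested.

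ERCC scaling gave 8165 genes for AZ5576, 5629 for THZ531, 5494 for OTS964, 53 for LDC4297, 1 for dBET1 and 213 for A241. A further threshold of 1 on the log2 fold change gave 2034, 826, 805, 40, 20 and 234 in the same order and 934 for Panobinostat, by its construction. Without a filter the counts were 1032 (THZ531), 1136 (OTS964), 70 (LDC4297) and 161 (dBET1). Fits with the DMSO wells alone gave 29 (LDC4297), 2 (dBET1) and 303 (A241), no plate term 88 (LDC4297) and 34 (dBET1), and adjustment over all treatments 227 and 234. For dBET1 library size alone gave 113, DESeq2 109, limma-voom 160 and the stricter filter 102. The panel as reference gave 108 for dBET1 and 949 for A241. Single positions of AZ5576 gave 2018, 3229 and 2341, with fewer wells. Leaving out wells 1 at a time gave 19 to 143 genes (LDC4297), 446 to 1618 (THZ531), 586 to 1787 (OTS964), 0 to 108 (dBET1), 117 to 534 (A241) and 901 to 1929 (Panobinostat), the lowest always without a treated well, where the lone well is assumed to vary like the other groups; the count of 0, by edgeR, had 787 genes at an unadjusted p under 0.05. Counts for AZ5576 stayed between 4269 and 4940.

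The human to ERCC ratio of LDC4297 ran from -0.03 to 0.02 and that of Panobinostat from -0.03 to 0.04 without 1 well. Without the first column Panobinostat stood at -0.16 (adjusted p = 0.361) and AZ5576 passed at -0.56.

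Lists called by fry were 26 (AZ5576), 20 (THZ531), 16 (OTS964) and 20 (Panobinostat), a test that does not compare with other genes; with an estimated correlation 2 (OTS964) and 3 (dBET1) were. ERCC scaling moved the medians of glycolysis in AZ5576 (-0.506) and THZ531 (-0.644) and of heat shock (heat_shock in THZ531, -0.668) below 0. It turned ZNF genes (zinc_finger_ZNF in OTS964) to the upper side of all genes (median -1.137, adjusted p = 0.87). LDC4297 against YKL5124 gave 0 genes by edgeR with the stricter filter (293 at an unadjusted p under 0.05), and Panobinostat against Quisinostat 3. Similarity had a median r of 0.33 among genes with a mean log2 CPM of at least 5, and pairs of DMSO wells at the same position a median of 3 genes (0 to 394).

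With ERCC scaling these genes changed sign: HBG2 (-0.13), HBG1 (-0.14), LDHA (-0.22), GAPDH (-0.23), IFITM3 (-0.21) and IFITM1 (-0.19) in AZ5576, HBA1 in THZ531 (-0.16), and HBG1 (-0.18), HBA2 (-0.11), MT-ND5 (-0.1) and RPL29 (-0.21) in OTS964. Against the panel NFE2 did so in LDC4297 (-0.24) and dBET1 (-0.43). Among values of genes named in the main comparisons 1651 kept direction and call, 133 lost the call (53 of them without a treated well, 29 with ERCC scaling) and 13 changed sign. Among lists, with ERCC scaling, an estimated correlation or fry, 188 values kept both, 39 lost the call and 4 changed direction. By fry, which does not compare with other genes, 76 kept both and 1 lost the call. By camera, and so relative to all genes, 59 kept both with ERCC scaling, where 14 lost the call and 4 changed direction. With an estimated correlation 53 kept both and 24 lost the call. More medians changed sign with ERCC scaling, such as those of erythroid effectors in AZ5576 (-0.31), THZ531 (-0.57) and OTS964 (-0.47). Genes named in other treatments were not refitted.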

Other observations

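Chosen only after the result was seen was the test of treatment by plate. The correlation with BET inhibitors was planned before it was computed, but after the gene lists were seen.

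Okadaic acid raised FOS (6.98, SE 0.31), IER2 (2.8, SE 0.1) and JUNB (2.46), with 23 of 34 immediate early genes higher and 1 lower (26 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 2.87e-28). The vault RNA VTRNA1-3 fell (-4.26, SE 0.33). Phendione raised the chaperones HSPA1A (3.67, SE 0.08) and HSPA1B (3.47), which can share reads, and 12 of 18 heat shock genes (13 higher and 1 lower adjusted over the list alone, median 0.454, camera adjusted p = 8.97e-22), while MT-ND6, the mitochondrial mRNA of the light strand, fell (-3.25, SE 0.2). MT-ND6 also fell in ActD (-4.6, SE 0.18). JIB_04 raised DDIT4 (3.22, SE 0.1) and 8 of 20 stress genes (14 adjusted over the list alone, median 0.629, camera adjusted p = 1.47e-21). Under the LSD1 inhibitor GSK_LSD1_2HCl LMO2 stood at 1.3 over DMSO and VIM, an intermediate filament gene, at 1.29 (SE 0.11). The DMSO wells outside the first column lay at -1.38 in LMO2 from the 39 panel compounds, a group that includes this compound. The LMO2 value is thus about the size of that offset. In the mean of LMO2, KLF1, NFE2 and LYL1 its wells stood at -0.216 and -0.313 from the panel.

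GSK_J4_HCl and GSK_J1 differed in 3 genes by edgeR, all metallothioneins, whose products bind zinc, named after their values were seen: MT1G (-4.29, SE 0.75), MT2A (-2.94, SE 0.47) and MT1X (-2.28, SE 0.5) were lower in GSK_J1. The pair was chosen after the names were seen. The term for treatment by plate called 0 genes by edgeR in each main comparison (341 to 512 at an unadjusted p under 0.05). Except in AZ5576 each plate holds 1 treated well, so this says nothing about agreement of the plates.

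The difference of the DMSO wells from 1 part of the panel resembled that of BET inhibitors from the remaining part, so that no well is shared, with r across genes of 0.48 for IBET_762, rank 1 of 35 treatments, and 0.436 for JQ1, rank 2. Among genes with a mean log2 CPM of at least 5 IBET_762 stood highest (0.666), but A241 (0.595), dBET1 (0.57) and SGC_CBP30 (0.56) came before JQ1 (0.52). Genes are not independent replicates. This is consistent with a solvent acting on genes that BET inhibitors move, a hypothesis found and tested on the same data. Compounds of the CBP class stood near, so the likeness may not be special to BET inhibitors.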
